A study of Mus musculus with 22 samples.

How the data were processed

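The series held 22 one-colour arrays of total RNA: 15 from the ileum and 7 from the colon of male C57BL/6 mice on chow. The labels give young mice as 6 to 8 weeks old and aged mice as 24 months old. Flox names the control mice and iKO the SIRT1 mutants of the labels, which do not spell the abbreviation out or say which part of Sirt1 was deleted. Groups were young ileum flox (n = 4) and iKO (n = 4), aged ileum flox (n = 3) and iKO (n = 4), and aged colon flox (n = 3) and iKO (n = 4). The labels number the replicates without saying whether ileum and colon came from the same mouse.

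The deposited values were signal intensities from Agilent Feature Extraction, version 9.5 per the file headers, with background subtraction and detrending within each array and no scaling between arrays. The authors' series matrix equalled these scanner values, with a largest relative difference of 0, so it gave no separate analysis. Each array held 45018 spots, of which 43379 were not controls, for 41174 distinct probes. A gene table of mouse build GRCm38.p6 was used for names only: 22951 probes were named by accession, 6659 by symbol and 3109 by synonym, and 8455 kept the name in the array file. Neighbouring genes were found from the probe coordinates of the array itself (build mm7). This gave 27670 gene names, 8914 of them with several probes.

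The values analysed were log2 signals minus the 75th percentile of the array, and a gene was read from its brightest probe. Genes were tested where the probe was well above background on every array of at least 1 group. Where 1 group was not well above background, the fold is given as a lower bound against the background. Differences were tested with limma 3.58.1 in R 4.3.3, in 1 fit of the 15 ileum arrays, 1 of the 7 colon arrays and 1 of the 14 aged arrays of both tissues, and were called at an adjusted p (Benjamini and Hochberg) under 0.05. Errors are standard errors of the fit and levels are means with standard deviations. Jackknife errors of correlations were taken over all 22 arrays as 1 set, arrays outside the correlation included. They are therefore a rough spread and not a standard error within groups. Tables were handled with data.table, version 1.17.8, and pandas 2.3.3 with Python 3.11.15, and figures matplotlib 3.10.9.

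Groups of genes came from 35 lists fixed before the data were examined, together with the comparisons, the filter, the thresholds, the rule for naming genes and the alternatives, except 1 added later: position on the slide as a term. Lists were tested with camera at its preset correlation of 0.01, then with an estimated correlation, then with fry. Members were also counted after being adjusted over the list alone. The rule named Sirt1 and, per comparison, the passing genes with a symbol and a probe well above background on every array of the brighter group: the 12 largest differences each way, or 5 for an interaction. Where fewer than 5 passed in a direction, the 5 smallest p were named as not passing. From a list, members with the smallest p were named; the text takes genes from the top.

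Arrays sat on 4 slides for the ileum and 4 for the colon, so tissue and array run could not be told apart. Each young slide held 1 flox array at position 1 and 1 iKO array at position 2, and colon flox arrays sat at position 3 with iKO at position 4. Genotype and position therefore coincided in the young ileum and the colon. Aged ileum arrays all sat at positions 3 and 4, so age and position also coincided, and no fit could part them. In the aged ileum both genotypes sat at positions 3 and 4, but only 1 slide held both. Slide was run as a fixed factor and as a random block, and within-slide differences stand beside the results. The main fits did not pair arrays by replicate number, and replicate numbers as a block were only an alternative. Over 21 ileum pairs the residuals of equal numbers correlated between -0.36 and 0.37, 14 of them above 0.1, and 8 had their own number as best match. No chance level was set for these values, so they do not exclude a structure shared by number.

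The alternatives were quantile normalization, normexp background correction, no filter and a stricter filter on dim probes, each probe alone, the mean over probes, only the groups in the contrast, eBayes with trend and robust, array weights, slide, replicate block and each array left out. In a self-test, 100 genes were shifted by 1 and 100 by 2 log2 units on arrays drawn at random from the mean and residual spread of each gene. The young iKO comparison recovered 73 and 95 with 9 unchanged genes called, the aged ileum one 66 and 95 with 11, and the colon one 53 and 82 with 12. Flox ageing recovered 79 and 92 with 12 unchanged genes called, iKO ageing 79 and 94 with 7, and genotype by age 52 and 83 with 3. Genotype by tissue recovered 37 and 67 with 8 unchanged genes called, and colon against ileum 63 and 86 with 6. A list shifted by 0.5 was called in each of the 8 comparisons, and 1 unshifted list was called in genotype by tissue. Each gene was drawn on its own, so the self-test cannot show how often camera calls lists falsely where genes vary together.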

Results

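Messenger RNA was measured on 22 arrays of mouse ileum and colon. In the ileum 49.8% to 61.5% of spots per array were well above background and the 75th percentile of the signal lay between 918 and 1231. In the colon these were 70.4% to 79.7% and 1425 to 1751. Before scaling, the 75th percentile was 937 to 1115 on young flox and 918 to 1098 on young iKO ileum arrays. On aged flox and aged iKO ileum arrays it was 1182 to 1214 and 1132 to 1231, so young and aged ranges did not overlap. Arrays of 1 group correlated at 0.976 to 0.991 in the ileum and 0.984 to 0.989 in the colon. The first axis of a principal component analysis held 27.2% of the ileum variance, with every young array below and every aged array above its centre. Every young ileum array sat at position 1 or 2 of its slide and every aged one at position 3 or 4, so age and position could not be told apart. The first axis held 26.3% of the colon variance.

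Sirt1, the gene targeted in iKO mice, was read on every array by a probe that may lie outside the deleted part, in whole tissue. Its level, in log2 units against the 75th percentile of the array, was 0.92 ± 0.24 in young ileum flox (n = 4), 0.70 ± 0.04 in young iKO (n = 4), 0.82 ± 0.25 in aged ileum flox (n = 3) and 0.32 ± 0.04 in aged iKO (n = 4). In the colon it was 0.78 ± 0.02 in flox (n = 3) and 0.50 ± 0.15 in iKO (n = 4). The iKO level was 86.2% of flox in the young ileum (-0.21 ± 0.12, adjusted p = 0.999), 70.8% in the aged ileum (-0.50 ± 0.13, adjusted p = 0.177) and 82.1% in the colon (-0.28 ± 0.11, adjusted p = 0.623). A second Sirt1 probe gave 0.00, -0.10 and -0.13. With its brightest probe Sirt1 passed in none of these 3 comparisons. Within slides it differed by -0.44 to 0.04 in the young ileum, -0.77 on the 1 shared slide in the aged ileum and -0.45 to -0.11 in the colon.

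**Figure D1:**
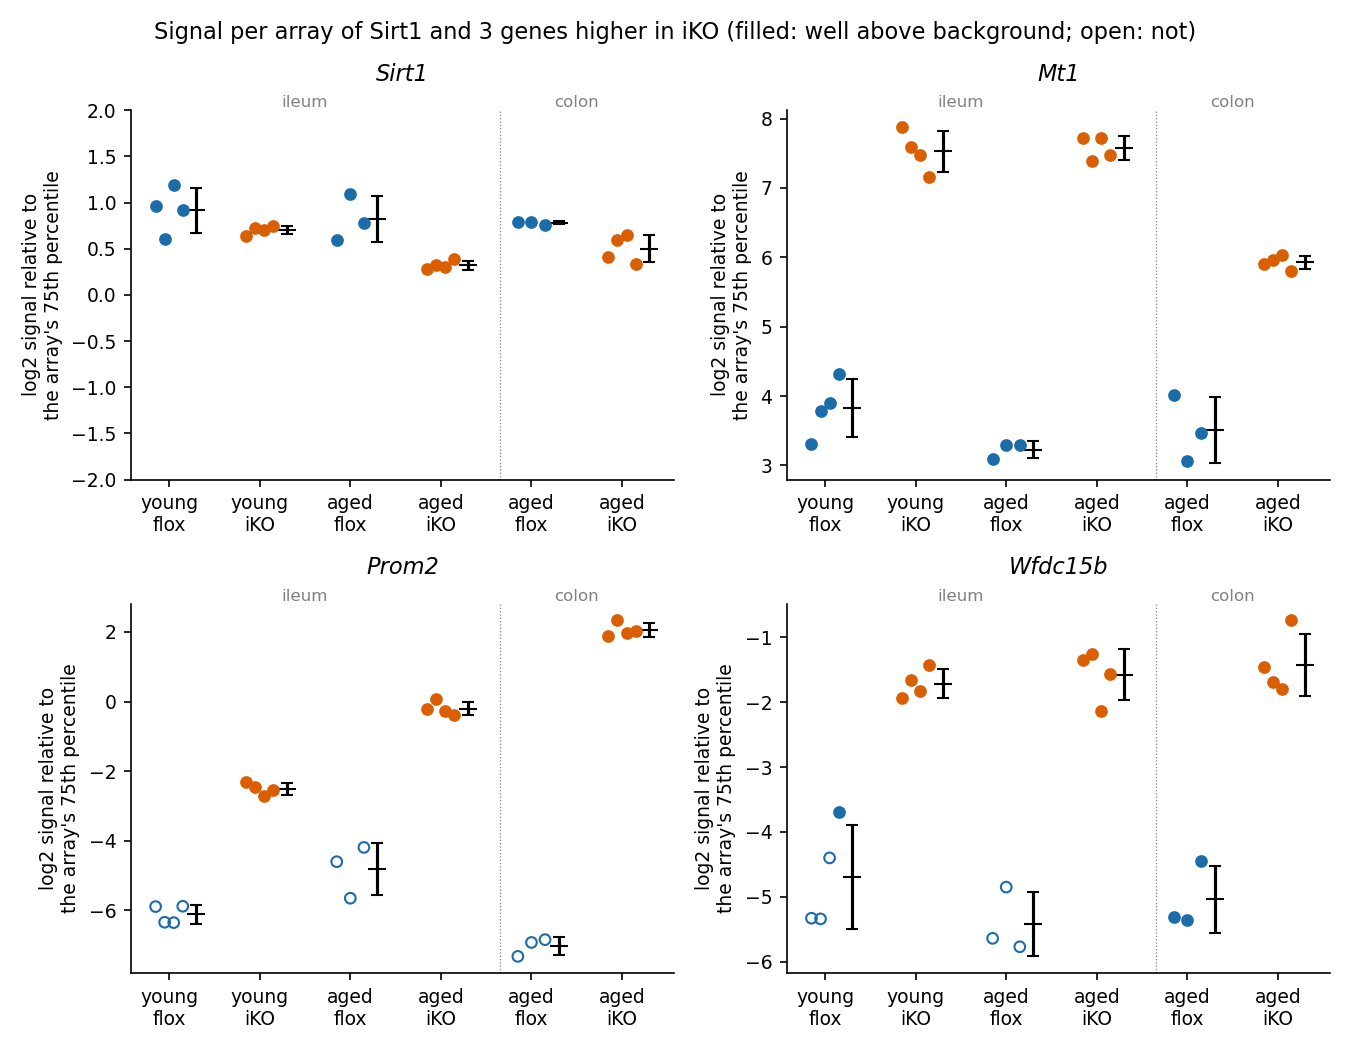
Level of Sirt1, Mt1, Prom2 and Wfdc15b on each array in the 6 groups, in log2 units against the 75th percentile of the array; filled points were well above background, bars show mean and standard deviation.

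In the young ileum, Mt1, a metallothionein that binds zinc and copper, rose 13.0-fold in iKO mice (3.70 ± 0.19, adjusted p = 5.71e-07), from 3.83 ± 0.41 (n = 4) to 7.53 ± 0.30 (n = 4). Prom2, a membrane protein related to prominin 1, rose at least 3.6-fold (3.61 ± 0.25, adjusted p = 1.02e-05), and no flox array was well above background. Wfdc15b, a protease inhibitor-like secreted protein, was higher (fitted 2.98 ± 0.34, adjusted p = 0.00216), but only 1 of 4 flox arrays was well above background, so its size is uncertain; normexp gave 1.66. Ankrd22 rose by 1.66 ± 0.15 (adjusted p = 0.000231). Slc44a2, a choline transporter-like protein, rose by 1.09 ± 0.16 and Il17re, a receptor subunit for interleukin 17C, by 1.04 ± 0.15 (adjusted p = 0.0208 for each). Pyroxd2 fell by 0.76 ± 0.08 (adjusted p = 0.000544). Second probes differed by 0.96 for Prom2, 0.11 for Ankrd22, 0.13 for Il17re and 0.10 for Pyroxd2. Within slides Mt1 differed by 3.16 to 4.28. Prom2 (3.17 to 4.03) and Wfdc15b (1.86 to 3.68) kept their direction there, with sizes that rest on background levels.

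These 6 higher genes and 1 lower gene were all that passed limma among 15488 tested in young iKO mice, with 641 at an unadjusted p under 0.05 against 774 by chance. With slide as a fixed factor 5 passed, and Slc44a2 and Il17re did not (adjusted p = 0.0536 for each). The count was 12 without aged iKO 2. Slc44a2 lost its call without each of young flox 1, 2, 3 and 4 and young iKO 1 and 2 (adjusted p = 0.0538 to 0.103). Il17re lost its call without each of young flox 1, 2 and 4 and young iKO 1 and 2 (adjusted p = 0.0825 to 0.104). With the mean over the probes of a gene 5 of the 7 did not pass: Prom2 (adjusted p = 0.124), Ankrd22 (0.42), Slc44a2 (0.0773), Il17re (0.58, adjusted p = 0.959) and Pyroxd2 (adjusted p = 1). With only the groups in the contrast Slc44a2 (adjusted p = 0.285), Il17re (0.246), Wfdc15b (0.0667) and Pyroxd2 (0.0692) did not pass. Slc44a2 and Il17re were also lost with no filter on dim probes (0.0775 for each). Ccdc198 did not pass (-1.44 ± 0.26, adjusted p = 0.0787), nor did Fpgs (-0.55 ± 0.10, adjusted p = 0.0787).

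Enteroendocrine markers leaned lower in young iKO ileum: 13 of 16 measured members were negative, with a median of -0.30. Examples were Pax4, a transcription factor of this lineage (-1.67 ± 0.38), and Chga, a granule protein (-0.56 ± 0.16). These were the 2 members that passed when adjusted over the list alone, and neither passed over all genes (adjusted p = 0.299 and 0.718). By camera the list passed (adjusted p = 0.00023; adjusted p = 0.783 with an estimated correlation), and its median was negative on each of the 4 slides (-0.55 to -0.23).

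Interferon response genes leaned higher in young iKO ileum, with all 23 members positive and a median of 0.34; 1 of them was Ifit3 (0.53 ± 0.24). By camera this passed (adjusted p = 0.00023; adjusted p = 0.788 with an estimated correlation). It did not pass without young flox 3 (median 0.13, adjusted p = 0.371) or young iKO 1 (0.15, adjusted p = 0.133), and slide medians ran from -0.60 to 0.76. B and plasma cell markers had a median of 0.82 with 12 of 12 positive, among them Blnk (0.33 ± 0.27) and Pou2af1 (0.70 ± 0.63). Their call (camera adjusted p = 0.0187; adjusted p = 0.788 with an estimated correlation) was lost without young flox 3 (median 0.52, adjusted p = 0.396) and young iKO 4 (-0.01, adjusted p = 0.875), the array whose mean stood 2.63 above the tissue. This call was also lost with a stricter filter (0.34, adjusted p = 0.0963) and array weights (0.57, 0.184), and the median was positive on 1 of 4 slides (-0.47 to 4.51). Fat and pancreas markers had a median of -1.41, among them Cfd (-3.35 ± 1.79) and Adipoq (-2.95 ± 1.66), which did not pass. Their call (camera adjusted p = 0.0258; adjusted p = 0.788 with an estimated correlation) was lost without young flox 2 (adjusted p = 0.131), young flox 3 (0.126), young iKO 3 (0.282) or young iKO 4 (0.144). It was also lost with a stricter filter on dim probes (median -0.24, adjusted p = 0.476), array weights (0.0504) and only the groups in the contrast (0.0692), with slide medians of -3.90 to 1.52.

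Camera passed 9 of 35 lists in the young ileum. Those not described above were tuft cell markers (median -0.25), epithelial antimicrobial defence (0.28) and NF-kB and inflammatory cytokines (0.32). Immediate early genes (0.19, positive on each of 4 slides) and Paneth cell markers (0.11) were also among them. Of 25 settings the tuft cell call was lost in 1, the NF-kB call in 2 and the antimicrobial call in 4. The immediate early and Paneth calls were lost in 3 each. With an estimated correlation 0 passed, with 1 at an unadjusted p under 0.05, and with fry 0 passed, with 2 at an unadjusted p under 0.05.

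In the aged ileum, Prom2 rose at least 17.1-fold in iKO mice (4.61 ± 0.27, adjusted p = 1.23e-06), Mt1 20.4-fold (4.35 ± 0.21, adjusted p = 1.87e-07) and Wfdc15b at least 6.6-fold (3.84 ± 0.37, adjusted p = 0.000271), with 4 iKO and 3 flox arrays. Bnipl rose at least 2.85-fold (3.33 ± 0.56, adjusted p = 0.03), Ankrd22 by 2.10 ± 0.16 (adjusted p = 3.37e-05), Hebp2, a haem-binding protein, by 1.62 ± 0.17 (adjusted p = 0.000856), Arhgap8 by 1.34 ± 0.18 (adjusted p = 0.00659) and Slc44a2 by 1.28 ± 0.17 (adjusted p = 0.00591). Ccdc198 fell by 2.35 ± 0.28 (adjusted p = 0.00201), Sult1c2, a sulfotransferase, by 1.78 ± 0.29 (adjusted p = 0.0291) and Lpar3, a receptor for lysophosphatidic acid, by 1.77 ± 0.16 (adjusted p = 0.000156), with 2 of 4 iKO arrays well above background. On the 1 slide with both genotypes Prom2 differed by 5.72, Mt1 by 4.09, Wfdc15b by 3.58, Slc44a2 by 1.35, ccdc198 by -2.94 and Lpar3 by -2.14, the Prom2 and Wfdc15b values against flox arrays at background. A second Prom2 probe differed the other way, by -0.36, and a second Ankrd22 probe by 0.35.

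In the aged ileum 18 genes were higher and 8 lower in iKO mice among 15488 tested, with 1849 at an unadjusted p under 0.05. Slide as a fixed factor gave 9, with Bnipl (adjusted p = 0.121), Arhgap8 (0.13) and Sult1c2 (-1.45, 0.463) lost, replicate number as a block 16, without Bnipl (0.0815). With only the groups in the contrast 13 passed, without Hebp2 (0.083), Arhgap8 (0.0931), ccdc198 (0.0768) and Sult1c2 (0.137). Position on the slide as a term, chosen after the data were seen and fitted to the aged ileum arrays alone, gave 5. The differences then stayed near their size, but Arhgap8 (1.36 ± 0.22, adjusted p = 0.253), Ankrd22 (2.04 ± 0.20, 0.114), Hebp2 (1.46 ± 0.20, 0.2), ccdc198 (-2.20 ± 0.32, 0.22), Sult1c2 (-1.87, 0.297) and Lpar3 (-1.76 ± 0.18, 0.117) did not pass. Of these, Ankrd22 and Lpar3 passed in the fit of the same arrays without the position term. The count was 44 without young flox 3, 46 without aged flox 1 and 15 without aged flox 4, and array weights gave 926. Bnipl lost its call without young iKO 2 and without each aged ileum array (adjusted p = 0.0538 to 0.123). Sult1c2 lost its call without aged flox 1 or 4 or aged iKO 1, 3 or 4 (adjusted p = 0.0618 to 0.0843). With the mean over probes Prom2 (adjusted p = 0.119) and Ankrd22 (1.23, 0.0687) did not pass, nor did Bnipl and Sult1c2 with no filter (0.0661 for each).

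By their brightest probes all 6 genes higher in young iKO ileum, Mt1, Prom2, Wfdc15b, Ankrd22, Slc44a2 and Il17re, were also higher in the aged ileum, and Pyroxd2 was lower in both. In the aged ileum second probes differed by -0.36 for Prom2, -0.51 for Il17re and 0.02 for Pyroxd2. Il17re lost its aged call without aged flox 4 or aged iKO 1, 2 or 3 (adjusted p = 0.0608 to 0.116), with slide as a fixed factor (0.107), replicate number as a block (0.0553), position as a term (0.17), the mean over probes (0.658) and no filter (0.0538). Pyroxd2 lost its call with slide as a fixed factor (adjusted p = 0.13), position (0.253), the mean over probes (0.492) and only the groups in the contrast (0.0823). Independent lists of these sizes would share 0.00697 higher genes, but both lists came from 1 fit with 1 spread per gene. Genes of low spread can be called in both, so that value is no chance level for them. Across 15488 genes the young and aged iKO differences correlated at r = 0.497 (Spearman 0.425). With no filter on dim probes r was 0.192, and leaving out 1 array gave 0.295 to 0.506, with a jackknife error of 0.233.

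Fibroblast and matrix genes leaned lower in aged iKO ileum, 14 of 15 with a median of -0.51. Examples were Col6a1, a collagen VI chain (-0.75 ± 0.15, adjusted p = 0.0749), and Mmp2, a matrix protease (-0.67 ± 0.22, adjusted p = 0.26); 7 members were lower when adjusted over the list alone. No smooth muscle, endothelial or enteric neuron and glia marker passed. Smooth muscle markers had a median of -0.26 (camera adjusted p = 0.00306; adjusted p = 0.652 with an estimated correlation) and endothelial markers had -0.26 (camera adjusted p = 0.0071; adjusted p = 0.652 with an estimated correlation). The smooth muscle call was lost without aged iKO 1 (-0.15, adjusted p = 0.0616), and the endothelial call without aged flox 1 (-0.15, adjusted p = 0.24) or aged iKO 2 (-0.13, adjusted p = 0.0777), with array weights (0.058) and with position as a term (0.0561). Enteric neuron and glia markers had a median of -0.28 and did not pass (camera adjusted p = 0.166; adjusted p = 0.793 with an estimated correlation). By camera the fibroblast list passed (adjusted p = 6.38e-06; adjusted p = 0.652 with an estimated correlation). Proximal small intestine genes leaned lower, 10 of 10 with a median of -0.55, among them Adh1 (-0.93 ± 0.17) and Cyp2c65 (-1.47 ± 0.47), and 3 passed when adjusted over the list alone (camera adjusted p = 0.00126; adjusted p = 0.652 with an estimated correlation). On the shared slide the medians were -0.19 for fibroblast, -0.05 for smooth muscle, -0.33 for endothelial, 0.12 for enteric neuron and glia and -0.77 for proximal genes.

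Cell cycle genes leaned higher in aged iKO ileum, 23 of 23 with a median of 0.25, among them Mki67 (0.37 ± 0.15) and Ccna2 (0.37 ± 0.15), which did not pass (camera adjusted p = 8.15e-05; adjusted p = 0.652 with an estimated correlation). Interferon response genes leaned higher, 23 of 23 with a median of 0.48, among them Mx2 (0.90 ± 0.38) and Isg15 (1.14 ± 0.48). That call (camera adjusted p = 0.000777; adjusted p = 0.652 with an estimated correlation) was lost with slide as a fixed factor (0.20, adjusted p = 0.252). Paneth cell markers had a median of 0.26, among them Mmp7 (0.81 ± 0.20) and Defa23 (0.33 ± 0.10), and their call (camera adjusted p = 0.000777; adjusted p = 0.652 with an estimated correlation) was also lost with slide (0.04, adjusted p = 0.694). On the shared slide the medians were 0.68 for cell cycle, 0.37 for interferon and -0.26 for Paneth genes. Xenobiotic and antioxidant genes had a median of -0.49, among them Ces2a (-0.92 ± 0.19) and Gsta1 (0.89 ± 0.27), and lost their call (camera adjusted p = 0.000777; adjusted p = 0.652 with an estimated correlation) with slide (-0.25, adjusted p = 0.0616; -0.14 on the shared slide). Enteroendocrine markers had a median of -0.34, among them Insl5 (-1.43 ± 0.30) and Chga (-0.74 ± 0.17), with 4 lower when adjusted over the list alone. Their call (camera adjusted p = 0.00306; adjusted p = 0.652 with an estimated correlation) was lost without aged flox 3 (-0.15, adjusted p = 0.0613), and their median was -0.30 on the shared slide.

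Camera passed 14 of 35 lists in the aged ileum. Those not described above were epithelial antimicrobial defence (median 0.79), NF-kB and inflammatory cytokines (0.27), unfolded protein response (0.19) and oxidative phosphorylation genes (0.11), leaning higher. PPAR-alpha and fatty acid oxidation genes (-0.18) leaned lower. Of 26 settings the antimicrobial and oxidative phosphorylation calls were lost in 3 each. The NF-kB call was lost in 5, the unfolded protein call in 6 and the PPAR-alpha call in 7. With an estimated correlation 0 passed, with 1 at an unadjusted p under 0.05, and with fry 0 passed, with 4 at an unadjusted p under 0.05.

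With age, Scgb2b20, a secretoglobin, rose in flox ileum at least 5.97-fold (4.51 ± 0.70, adjusted p = 0.00279), Sult1e1, an oestrogen sulfotransferase, at least 5.05-fold (3.27 ± 0.50, adjusted p = 0.00251) and Ces1g, a carboxylesterase, by 3.07 ± 0.71 (adjusted p = 0.0218), with 3 aged and 4 young arrays. Rps4l, a ribosomal protein gene, fell by 4.50 ± 0.13 (adjusted p = 1.89e-10), and Kifc5b (-4.31 ± 0.21, adjusted p = 5.07e-08), Tmem242 (-3.99 ± 0.11, adjusted p = 1.89e-10) and Cldn4, a tight junction claudin (-3.89 ± 0.37, adjusted p = 3.2e-05), fell too, with Kifc5b well above background on 1 of 3 aged arrays. Sirt1 did not pass (-0.10 ± 0.13, adjusted p = 0.678). Ces1g lost its call without young flox 1 or 4 or aged flox 1 or 4 (adjusted p = 0.0561 to 0.0901) with slide as a fixed factor (0.0901) and with no filter on dim probes (0.0573).

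With age, Sult1e1 rose in iKO ileum at least 2.31-fold (2.39 ± 0.46, adjusted p = 0.00832), Prom2 by 2.30 ± 0.25 (adjusted p = 0.000107) and Fetub, a protease inhibitor, at least 3.45-fold (2.25 ± 0.28, adjusted p = 0.000441), with 4 arrays per age. Rps4l fell by 4.42 ± 0.12 (adjusted p = 8.88e-11), Bhmt2, a homocysteine methyltransferase, at least 8.9-fold (-4.33 ± 0.40, adjusted p = 2.47e-05), and Cldn4 (-4.15 ± 0.34, adjusted p = 8.59e-06) and Dnajb3 (-4.04 ± 0.19, adjusted p = 2.82e-08) fell too, these last each well above background on 3 of 4 aged arrays. Sirt1 did not pass (-0.38 ± 0.12, adjusted p = 0.0605). With the mean over its probes Prom2 did not pass (adjusted p = 0.144), and its second probe differed by -0.18.

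In the flox ileum 492 genes were higher and 831 lower with age among 15488 tested, and in the iKO ileum 799 and 865. The higher genes shared 317, against 25.4 for independent lists, and the lower ones 482, against 46.4, with no gene called in opposite directions. Both comparisons set positions 3 and 4 against positions 1 and 2 of the slides, and arrays of higher signal before scaling against arrays of lower signal. They also came from 1 fit with 1 spread per gene, so their lists were not independent. With quantile normalization the splits were 461 and 441 in flox mice and 843 and 570 in iKO mice. Slide as a fixed factor gave 475 in flox mice and 1361 in iKO mice. The mean over probes gave 829 and 1069, only the groups in the contrast 507 and 1055, and no filter 399 and 663. Array weights gave 3276 in flox mice. In flox mice the count was 679 without young flox 1, 840 without young flox 3, 516 without young flox 4, 519 without aged flox 1, 875 without aged flox 3 and 439 without aged flox 4. In iKO mice it was 1077 without young iKO 2, 638 without young iKO 3, 696 without aged iKO 1, 758 without aged iKO 3 and 947 without aged iKO 4.

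**Figure D2:**
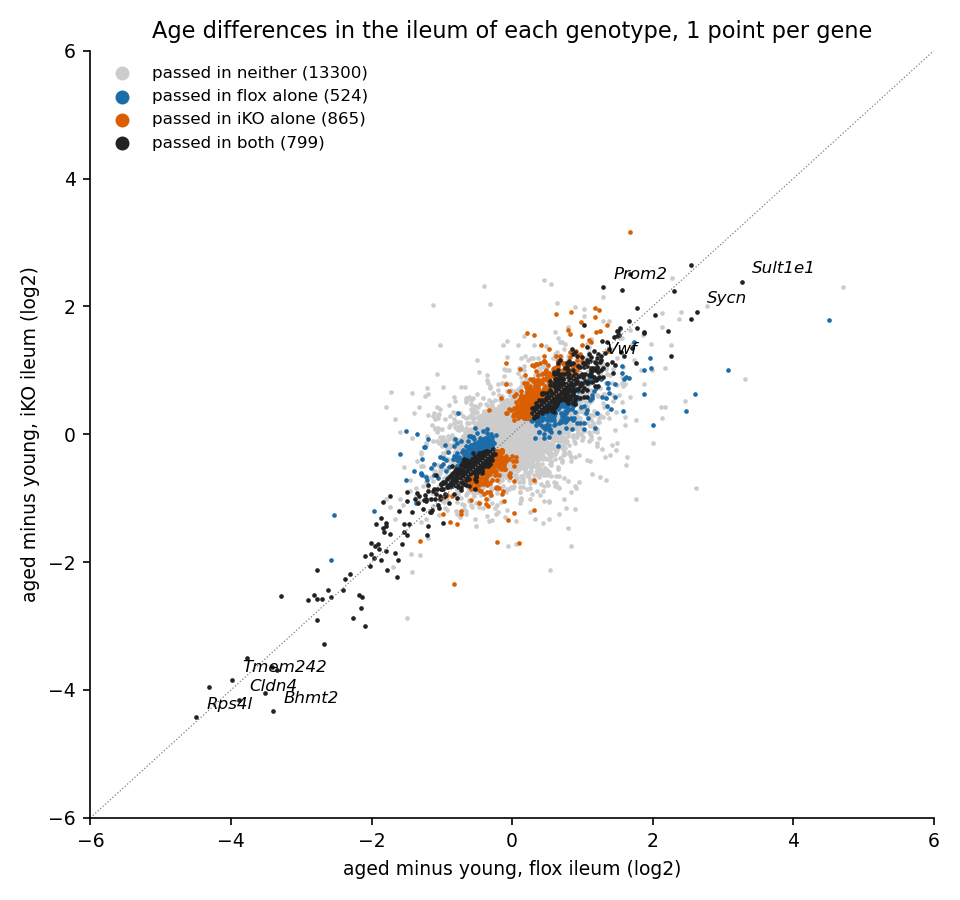
Difference between aged and young ileum in flox mice and in iKO mice for each of 15488 genes, coloured by the genotypes in which it passed.

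Oxidative phosphorylation genes fell with age: in flox mice 11 of 27 members passed as lower and none as higher, among them Cox7a2, a cytochrome oxidase subunit (-0.49 ± 0.11, adjusted p = 0.0226), and Cycs, cytochrome c (-0.61 ± 0.14, adjusted p = 0.0229). The median was -0.29 (camera adjusted p = 6.48e-09; adjusted p = 0.708 with an estimated correlation) and -0.34 on both shared slides. Cox7a2 lost its call without young flox 1 or 4 or aged flox 1, 3 or 4 (adjusted p = 0.0508 to 0.0696), Cycs without young flox 1 or aged flox 3 or 4 (0.0575 to 0.0758), and both with slide as a fixed factor (0.0828 and 0.105). With quantile normalization neither passed (Cox7a2 -0.28, adjusted p = 0.125; Cycs -0.37, 0.0819). In iKO mice 6 members passed as lower, among them Ndufa2 (-0.43 ± 0.09) and Ndufa1 (-0.39 ± 0.09), with a median of -0.19 (camera adjusted p = 5.78e-05; adjusted p = 0.768 with an estimated correlation). Ndufa1 lost its call without young iKO 3 (adjusted p = 0.051) or aged iKO 1 (0.0514). With quantile normalization Ndufa2 (-0.27, adjusted p = 0.0808), Ndufa1 (-0.21, 0.11) and the iKO list (median -0.01, 0.376) lost their calls; the iKO slide medians were -0.38 to -0.08.

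Cholesterol synthesis genes fell with age, 9 of 24 in flox mice and 6 in iKO mice. Fdps, farnesyl diphosphate synthase, fell by 0.91 ± 0.11 (adjusted p = 0.0004) in flox mice and by 0.82 ± 0.10 (adjusted p = 0.000494) in iKO mice. The medians were -0.42 in flox mice (camera adjusted p = 5.14e-07; adjusted p = 0.708 with an estimated correlation) and -0.32 in iKO mice (camera adjusted p = 3.99e-06; adjusted p = 0.768 with an estimated correlation). With the mean over its probes Fdps did not pass in either (adjusted p = 0.212 and 0.444). Slide medians ran from -0.56 to -0.03 in flox mice and from -0.43 to -0.23 in iKO mice.

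Endothelial markers rose with age, 5 of 10 in flox mice and 3 in iKO mice. Vwf, von Willebrand factor, rose by 1.20 ± 0.11 (adjusted p = 3.64e-05) and 1.12 ± 0.11 (adjusted p = 3.05e-05), and Eng, endoglin, by 0.85 ± 0.13 (adjusted p = 0.00208) and 0.66 ± 0.12 (adjusted p = 0.00528). The medians were 0.68 in flox mice (camera adjusted p = 3.17e-06; adjusted p = 0.708 with an estimated correlation) and 0.48 in iKO mice (camera adjusted p = 0.000118; adjusted p = 0.768 with an estimated correlation). With the mean over its probes Vwf did not pass in iKO mice (adjusted p = 0.125). Slide medians were 0.44 to 0.75 in flox mice and 0.15 to 0.86 in iKO mice. Macrophage and neutrophil markers rose, 2 of 14 in flox mice, Cd68 (1.03 ± 0.23) and Cd163 (1.29 ± 0.30), and 3 in iKO mice, among them Csf1r (0.77 ± 0.18) and Cd163 (1.04 ± 0.28). Cd68 lost its call without aged flox 1 or 4 (adjusted p = 0.062 and 0.0788), and Cd163 in flox mice without young flox 1 or 3 or aged flox 1 or 4 (0.0503 to 0.0799). In iKO mice Csf1r lost its call without aged iKO 1, 3 or 4 (0.0538 to 0.0604) and Cd163 without young iKO 1 or 3 or aged iKO 3 or 4 (0.0584 to 0.09). With slide as a fixed factor none of these calls was kept, and with the mean over its probes Csf1r did not pass in iKO mice (0.14, adjusted p = 0.808). Their flox call (camera adjusted p = 0.00325; adjusted p = 0.823 with an estimated correlation) was lost without young flox 3 (median 0.33, adjusted p = 0.0517). Their iKO call (camera adjusted p = 0.0229; adjusted p = 0.768 with an estimated correlation) was lost without aged flox 1 (adjusted p = 0.0512), aged iKO 3 (0.0927) or aged iKO 4 (0.0798) and with slide (0.0648). Slide medians were 0.04 to 1.04 in flox mice and -0.11 to 0.73 in iKO mice.

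Paneth cell markers fell with age, 4 of 20 in flox mice, among them the defensins Defa23 (-0.48 ± 0.10, adjusted p = 0.0145) and Defcr-rs12 (-1.29 ± 0.27, adjusted p = 0.0159). In iKO mice 2 fell, Defcr6 (-0.42 ± 0.11, adjusted p = 0.0286) and Defcr4 (-0.31 ± 0.09, adjusted p = 0.0377). Defa23 and Defcr-rs12 lost their calls without aged flox 1 or 4 (adjusted p = 0.0609 to 0.0719) and with slide as a fixed factor (0.0685 and 0.0552), and Defa23 with quantile normalization (-0.23, 0.0631). Defcr6 lost its call without young iKO 1, 2 or 3 or any 1 aged iKO array (0.0537 to 0.0915) and with quantile normalization (-0.13, 0.264). Defcr4 lost its call without young flox 4, young iKO 1, 2 or 3, aged flox 4 or any 1 aged iKO array (0.0512 to 0.104), with slide (0.0568), the mean over probes (0.0529) and quantile normalization (-0.07, 0.521). The medians were -0.41 in flox mice (camera adjusted p = 3.32e-06; adjusted p = 0.823 with an estimated correlation) and -0.32 in iKO mice (camera adjusted p = 9.49e-05; adjusted p = 0.768 with an estimated correlation). Slide medians were -0.60 and 0.02 in flox mice and -0.53 to -0.31 in iKO mice, and the iKO call was lost with quantile normalization (-0.10, adjusted p = 0.174).

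MHC class II genes leaned higher with age, with medians of 0.77 in flox mice (camera adjusted p = 0.00325; adjusted p = 0.823 with an estimated correlation) and 0.71 in iKO mice (camera adjusted p = 0.00623; adjusted p = 0.768 with an estimated correlation). Cd74, the invariant chain, differed by 0.83 ± 0.32 in flox mice (adjusted p = 0.123) and 1.01 ± 0.30 in iKO mice (adjusted p = 0.0471). The iKO call of Cd74 was lost without young flox 4, young iKO 2, 3 or 4 or any 1 aged ileum array (adjusted p = 0.0577 to 0.131), with slide as a fixed factor (0.095), with the mean over probes (0.0591) and with no filter on dim probes (0.11). Slide medians of the list were 0.52 to 1.73 in flox mice and 0.07 to 1.27 in iKO mice. The calls with age of Cox7a2, Cycs, Cd68 and Defa23 in flox mice, of Ndufa1, Csf1r, Defcr4 and Defcr6 in iKO mice, and of Cd163 in both were also lost with no filter. With only the groups in the contrast Cycs (0.0503), Cd68 (0.0575), Defa23 (0.0536) and Defcr-rs12 (0.0672) in flox mice were lost, as were Ndufa1 (0.0543), Cd163 (0.0618), Defcr6 (0.059) and Defcr4 (0.0847) in iKO mice. H2-Aa did not pass in either (1.10 ± 0.41 and 1.20 ± 0.38). Camera passed 8 of 35 lists in each genotype. Those not described above were brush border genes, lower in both (medians -0.31 in flox and -0.37 in iKO mice), colon region genes, higher in flox mice (0.56), and smooth muscle markers, lower in iKO mice (-0.25). The brush border call was lost in 11 of 25 settings in flox mice and 4 in iKO mice, the colon region call in 3 and the smooth muscle call in 8. With an estimated correlation 0 passed in either, with 2 at an unadjusted p under 0.05 in flox mice and 1 in iKO mice, and fry passed 5 and 4.

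**Figure D3:**
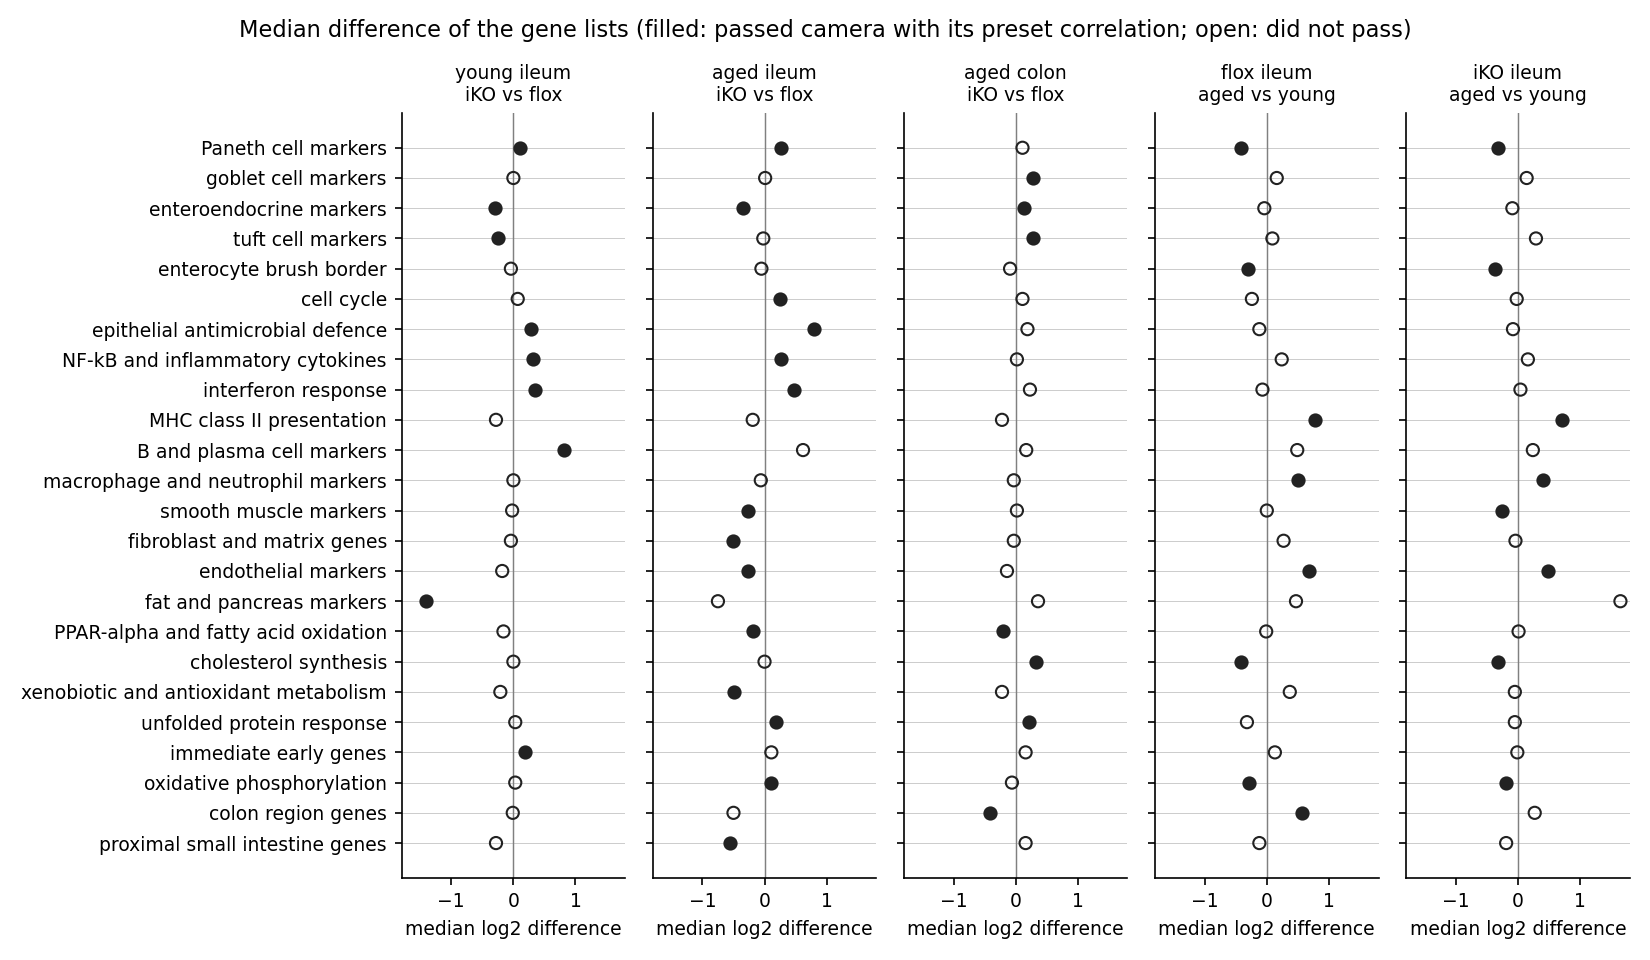
Median difference of the genes of each list in 5 comparisons; filled points passed camera at the preset correlation.

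The young iKO difference and the ageing difference of flox mice, which share the young flox arrays, correlated at r = 0.019 (Spearman -0.07, covariance 0.00195). Simulated groups without effects, each gene drawn on its own, gave r = 0.462 and a covariance of 0.0308, so the observed covariance was lower by 0.0289. With the flox arrays split r averaged -0.194 (-0.319 to -0.009). Across the settings r turned to -0.015 with normexp and -0.049 with a stricter filter on dim probes. Leaving out 1 array gave -0.049 to 0.203, with a jackknife error of 0.26.

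Genes whose iKO difference changed with age were sought in the ileum, and none passed limma: 0 of 15488, with 391 at an unadjusted p under 0.05 against 774 by chance. Lpar3 had the smallest p (-1.28 ± 0.22, adjusted p = 0.712), and B4galnt4 (0.71 ± 0.15) and Mthfd2 (0.73 ± 0.17) had an adjusted p of 1. Sirt1 differed by -0.28 ± 0.18 (adjusted p = 1). The count was 4 without aged flox 1, 1 without aged flox 4 and 1 with normexp. Fibroblast and matrix genes leaned lower, 14 of 15 with a median of -0.47, among them Col6a1 (-0.53 ± 0.20) and Sparc (-0.54 ± 0.30), both with an adjusted p of 1 (camera adjusted p = 1.6e-06; adjusted p = 1 with an estimated correlation). Camera passed 5 of 35 lists. Those not described above were cell cycle and oxidative phosphorylation genes, leaning higher, and smooth muscle and xenobiotic genes, leaning lower. Of 24 settings these calls were lost in 6, 9, 4 and 11. With an estimated correlation and with fry 0 lists passed, with 0 at an unadjusted p under 0.05.

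In the colon of aged mice, Prom2 rose at least 332-fold in iKO mice (9.08 ± 0.16, adjusted p = 2.35e-06; 4 iKO and 3 flox arrays), by 8.82 to 9.34 within slides against flox arrays at background and by 4.44 on a second probe. Syt8, a synaptotagmin, rose by 4.59 ± 0.47 (adjusted p = 0.0246), Wfdc15b by 3.62 ± 0.32 (adjusted p = 0.0134), Rnf225 at least 4.15-fold (3.40 ± 0.29, adjusted p = 0.0134), Zfp185, a LIM domain protein, by 2.96 ± 0.25 (adjusted p = 0.0134) and Tnni2, a troponin subunit, by 2.88 ± 0.20 (adjusted p = 0.00559). Mt1 rose by 2.41 ± 0.21 (adjusted p = 0.0134; 1.80 to 2.89 within slides), Nectin4, an adhesion protein, by 1.96 ± 0.20 (adjusted p = 0.0228) and Slc44a2 by 1.42 ± 0.10 (adjusted p = 0.00559; 1.31 to 1.64 within slides). Cxcl11, a chemokine, fell at least 3.89-fold (-2.66 ± 0.29, adjusted p = 0.03) and Mycn, a transcription factor, by 2.20 ± 0.19 (adjusted p = 0.0134).

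In the colon 18 genes were higher and 4 lower in iKO mice among 19588 tested, with 1413 at an unadjusted p under 0.05 against 979 by chance. Prom2 alone passed with slide as a fixed factor (1 gene), so none of the other genes named here did, and with replicate number as a block 1 passed. With slide the other differences stayed near their size (Mt1 2.42, Wfdc15b 3.63, Tnni2 2.88, Mycn -2.05), in a fit of 7 arrays with slide terms added. Normexp gave 45 and eBayes with trend and robust 48. The count was 11 without colon flox 1, 10 without flox 3, 7 without iKO 1, 5 without iKO 2, 14 without iKO 3 and 11 without iKO 4. Syt8 lost its call without flox 3 or 4 or any 1 iKO array (adjusted p = 0.0639 to 0.147), and Wfdc15b without flox 1 or 3 or iKO 1 or 2 (0.0725 to 0.0953). Rnf225 lost its call without flox 1 or 3 or iKO 1, 2 or 4 (0.054 to 0.0953), and Mt1 without flox 4 or any 1 iKO array (0.0532 to 0.0978). Cxcl11 lost its call without flox 1, 3 or 4 or iKO 1 or 2 (0.104 to 0.163), and Mycn without flox 1, 3 or 4 or iKO 2 or 3 (0.0518 to 0.0953). Zfp185 lost its call without flox 3 or 4 or iKO 1, 2 or 3 (0.0518 to 0.0953), and Nectin4 without flox 1, 3 or 4 or iKO 1, 2 or 3 (0.0581 to 0.134). Prom2, Tnni2 and Slc44a2 passed without each array. Cxcl11 was lost with quantile normalization (0.0785), Nectin4 (0.148) and Mycn (0.0614) with the mean over probes, and Syt8 (0.0568), Nectin4 (0.0514) and Cxcl11 (0.0639) with no filter.

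Mt1, Prom2, Slc44a2 and Wfdc15b rose in both the aged ileum and the colon, 4 genes against 0.0164 for independent lists, and no lower gene was shared. Across 15407 genes the iKO differences of ileum and colon correlated at r = 0.235 (Spearman 0.27), with a jackknife error of 0.162. Leaving out 1 array gave 0.11 to 0.303. Regrouping the 7 aged ileum arrays gave a value as far from 0 in 3 of 35 groupings, the largest other being 0.254.

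Goblet cell markers leaned higher in iKO colon, 17 of 19 with a median of 0.28, among them Spink4 (1.01 ± 0.23) and Ern2 (0.58 ± 0.19), and none passed over all genes or adjusted over the list alone. By camera the list passed (adjusted p = 4.33e-06; adjusted p = 0.799 with an estimated correlation), with slide medians of 0.10 to 0.56. Cholesterol synthesis genes leaned higher, 21 of 24 with a median of 0.33, among them Mvd (0.86 ± 0.18) and Pmvk (0.44 ± 0.12), and that call (camera adjusted p = 4.33e-06; adjusted p = 0.799 with an estimated correlation) was lost without colon flox 4 (0.12, adjusted p = 0.252), with slide medians of -0.04 to 0.64. Colon region genes leaned lower, 15 of 18 with a median of -0.42, among them the homeobox genes Hoxa13 (-2.89 ± 0.50) and Hoxd10 (-1.21 ± 0.22), which passed when adjusted over the list alone (0.00763 for each) but not over all genes (0.165 and 0.18). That call (camera adjusted p = 0.00183; adjusted p = 0.799 with an estimated correlation) was lost without colon flox 1 (-0.44, adjusted p = 0.0571), with slide medians of -1.25 to 0.05, positive on 1 of 3. Camera passed 7 of 35 lists in the colon. Those not described above were tuft cell (median 0.28), enteroendocrine (0.13) and unfolded protein response genes (0.21), leaning higher, and PPAR-alpha and fatty acid oxidation genes (-0.20), leaning lower. Of 16 settings the tuft cell call was lost in 4, the enteroendocrine call in 5 and the other calls in 1 each. With an estimated correlation 0 passed, with 0 at an unadjusted p under 0.05, and with fry 0 passed, with 2 at an unadjusted p under 0.05.

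Tested for a different iKO effect in colon and ileum of aged mice, Tnni2 rose more in the colon (2.73 ± 0.31, adjusted p = 0.00927) and Mt1 rose less there (-1.94 ± 0.25, adjusted p = 0.0249). Prom2 (adjusted p = 0.00121) and Rnf225 (adjusted p = 0.0306) also passed, but no size is given for them. Prom2 was not well above background on any flox array of either tissue, nor Rnf225 on any colon flox array, so part of the fitted difference lies between background levels. In iKO mice Prom2 stood at 2.05 ± 0.20 in the colon (n = 4) and -0.21 ± 0.19 in the ileum (n = 4). Of 19640 genes 5 were higher and 2 lower, with 1177 at an unadjusted p under 0.05 against 982 by chance, and with normexp the split was 2 and 3. With replicate number as a block 0 passed by limma, with 1159 at an unadjusted p under 0.05. With slide as a fixed factor 3 passed, none of them a gene called in the main fit. Prom2 (adjusted p = 0.0729), Tnni2 (0.321), Rnf225 (0.321) and Mt1 (0.372) did not pass. The count was 4 without each of ileum flox 3, ileum flox 4, ileum iKO 1, colon flox 1 and colon iKO 4, 3 without each of ileum iKO 4, colon iKO 1 and colon iKO 2, and 11 without colon flox 4. Rnf225 lost its call without any 1 aged array but colon flox 4 and ileum iKO 3 (adjusted p = 0.0526 to 0.127). Mt1 lost its call without ileum flox 1, 3 or 4, ileum iKO 1, 3 or 4 or colon iKO 1, 2 or 4 (0.0566 to 0.0942). Rnf225 was also lost with normexp (0.71, adjusted p = 0.15) and eBayes with trend and robust (0.0706), and both genes with no filter (0.0559 and 0.0523).

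Oxidative phosphorylation genes leaned lower in this test, 26 of 27 with a median of -0.18, among them Ndufs1 (-0.58 ± 0.18) and Cycs (-0.57 ± 0.20), which did not pass (camera adjusted p = 7.26e-06; adjusted p = 0.66 with an estimated correlation). Enteroendocrine markers leaned higher, 17 of 19 with a median of 0.48, among them Insl5 (2.50 ± 0.59, adjusted p = 0.446; 0.022 adjusted over the list alone) and Pax6 (1.30 ± 0.52), with a camera adjusted p = 6.25e-05 (adjusted p = 0.66 with an estimated correlation). Fibroblast and matrix genes had a median of 0.42, among them Col6a1 (0.97 ± 0.22) and Col1a1 (0.65 ± 0.20), and lost their call (camera adjusted p = 7.26e-06; adjusted p = 0.66 with an estimated correlation) with slide (0.13, adjusted p = 0.11). Camera passed 10 of 35 lists. Those not described above were goblet, tuft cell, smooth muscle, fat and pancreas and cholesterol synthesis genes, leaning higher, and NF-kB and T cell genes, leaning lower. Of 23 settings the T cell call was lost in 9, the NF-kB call in 8 and the tuft cell call in 7. The smooth muscle call was lost in 3 and reversed in 1, the fat call was lost in 3 and the others in 1 each. With an estimated correlation 0 passed, with 2 at an unadjusted p under 0.05, and with fry 0 passed, with 1 at an unadjusted p under 0.05.

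Between colon and ileum of aged flox mice, Hoxb13, a homeobox gene of the hindgut, was at least 233-fold higher in the colon (9.79 ± 0.46, adjusted p = 8.01e-08; 3 arrays each), Fxyd4, an ion transport regulator, at least 185-fold (9.45 ± 1.25) and Tgm3, a transglutaminase, at least 140-fold (8.98 ± 0.58). Defa22, a Paneth cell defensin, was at least 9820-fold lower (-14.17 ± 0.62, adjusted p = 4.17e-08), and Defa29 (-13.42 ± 0.35) and Apoa1, the main apolipoprotein of HDL (-12.54 ± 0.53; well above background on 2 of 3 colon arrays), were lower too. Sirt1 did not differ (-0.04 ± 0.12, adjusted p = 0.839). Among 19640 genes 3760 were higher and 2700 lower in the colon, 2886 and 3712 with normexp and 10906 in all with no filter.

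Paneth cell markers were lower in the colon, 18 of 19 with a median of -10.59 and 1 higher, among them Defa29 and Defa21 (-13.25 ± 0.39), by camera (adjusted p = 1.8e-20; adjusted p = 0.0201 with an estimated correlation). Brush border genes were lower, 18 of 20, among them the peptidases Anpep (-8.00 ± 0.20) and Enpep (-6.24 ± 0.33; camera adjusted p = 7.07e-18; adjusted p = 0.102 with an estimated correlation). Lipid absorption genes were lower, 17 of 20, among them Mttp (-7.46 ± 0.24) and Apoa1 (camera adjusted p = 8.27e-15; adjusted p = 0.0776 with an estimated correlation). MHC class II genes were lower, 8 of 9, among them H2-DMb1 (-3.55 ± 0.29) and H2-DMa (-3.92 ± 0.32; camera adjusted p = 1.49e-08; adjusted p = 0.262 with an estimated correlation). Colon region genes were higher, 14 of 18, among them Hoxb13 and Sycn (7.11 ± 0.52; camera adjusted p = 3.41e-08; adjusted p = 0.163 with an estimated correlation). Camera passed 13 of 35 lists, 1 with an estimated correlation, and fry 16. Those not described above were cell cycle, NF-kB, interferon, T cell, macrophage, bile acid, cholesterol and unfolded protein response genes, all leaning lower. Of 23 settings the NF-kB call was lost in 3, the unfolded protein call in 2 and the bile acid call in 1. No slide held both tissues, so these differences include any difference between array runs.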

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

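The test of genes near 1 inserted stretch was chosen only after the result was seen. Groups of 4 arrays were searched for an array far from the other 3 in signal and in the levels of named genes; 4 of 65 groups tested had one, and chance gives about 1 in 20.

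Young ileum iKO 4 had a 75th percentile signal of 1098 where the other 3 arrays of its group had 918 to 938, and a median signal of 111.6 where they had 98 to 99.1. In aged ileum iKO 4, Il17re stood at 1.31 where the other 3 arrays had 1.62 to 1.68. In aged colon iKO 4, Zfp185 stood at -1.04 where the other 3 had -0.28 to -0.15.

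The difference between iKO and flox differed between colon and ileum for 7 genes by an interaction test. Colon minus ileum was 2.73 ± 0.31 for Tnni2 (2.88 in the colon, 0.16 in the ileum) and -1.94 ± 0.25 for Mt1 (2.41 and 4.35). The fit also gave 4.47 for Prom2 and 3.04 for Rnf225, which are not measured sizes: Prom2 was not well above background on any flox array, nor Rnf225 on any colon flox array. For 3 probes named only by an accession the fit gave 4.96, -4.67 and 1.13. With replicate number as a block none of the 7 passed by limma, where 1159 genes had an unadjusted p under 0.05.

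Mt1 was higher in iKO mice in the young ileum, the aged ileum and the colon by 3.70, 4.35 and 2.41, and a second Mt1 probe by 4.34, 5.47 and 3.34. Mt2, its neighbour under the same metal and stress control, differed by -0.28 ± 0.63, 0.41 ± 0.68 and -0.92 ± 0.58, with a largest upper 95% limit of 1.86, below 50% of the Mt1 difference in the same set; this argues against raised transcription of the metallothionein genes. Position on the slide is argued against by the aged ileum, where Mt1 differed by 4.38 ± 0.14 (adjusted p = 0.000661) with position as a term. Within position 3 it differed by 4.52 (1 iKO array against 2 flox) and within position 4 by 4.25 (3 against 1), each with an arm of 1 array; its ordinary aged ileum difference had been seen when this test was set. The excess of Mt1 over Mt2 was at least 3.33 in each set. An excess above 1, with every Mt1 probe higher, had been set as needed if the construct that makes the knockout carries Mt1 sequence, and this hypothesis stays open. A rise of Mt1 alone through loss of SIRT1 was not tested apart from it.

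Of the genes called in any of the 3 iKO comparisons, 44 in all, 6 had another within 2 Mb, among them Syt8 beside Tnni2 and Mt1 beside Pllp. Random sets had a median of 4 and as many in a share of 0.43, so genes near 1 inserted or carried stretch of DNA cannot be told apart from chance by this count. With position as a term in the aged ileum, 7 of the 7 genes called in the young ileum passed with the same sign. They were read from their brightest probes and adjusted over these genes alone. All 7 had been called in the aged ileum without that term, and those differences had been seen, so this pass was likely beforehand. Within positions 3 and 4, each with an arm of 1 array, all 7 kept their sign, among them Il17re (1.04 and 1.11) and Pyroxd2 (-0.48 and -0.73). This argues against positions 3 and 4 as their source there, and does not cover positions 1 and 2. Adjusted over all genes, Ankrd22 (2.10 ± 0.16 before, 2.04 with position), Il17re and Pyroxd2 (-0.62 ± 0.08 before, -0.61 with position) did not pass with position as a term. In a fit of the same arrays without that term Ankrd22 and Il17re passed, and Pyroxd2 did not (limma adjusted p = 0.0823).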

How the results depend on the processing

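Position on the slide as a term was chosen only after the result was seen, and it gave 5 genes for iKO in the aged ileum. Every count of genes stayed within 1.5 times with each probe on its own and with slide as a random block. The counts that moved further follow, and the cause was not tested.

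For young iKO, quantile normalization gave 13 genes, the mean over the probes of a gene 3, only the groups in the contrast 3, and eBayes with trend and robust 14. For aged ileum iKO, only the groups in the contrast gave 13, array weights 926, slide as a fixed factor 9 and the replicate block 16. For ageing in flox mice, no filter on dim probes gave 399, the mean over probes 829, only the groups in the contrast 507, array weights 3276 and slide as a fixed factor 475. For ageing in iKO mice, no filter gave 663, the mean over probes 1069 and only the groups in the contrast 1055. For genotype by age, normexp background correction gave 1. For colon iKO, normexp gave 45, eBayes with trend and robust 48, slide as a fixed factor 1 and the replicate block 1. For genotype by tissue, no filter gave 4, a stricter filter on dim probes 2, slide as a fixed factor 3 and the replicate block 0 by limma, with 1159 at an unadjusted p under 0.05. For colon against ileum, no filter gave 10906; slide could not be fitted there, since no slide held both tissues. The counts from array weights depend on the order of the genes in the table.

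Leaving out 1 array at a time gave 5 to 12 genes for young iKO, 15 to 46 for aged ileum iKO, 439 to 1430 for ageing in flox mice, 638 to 1758 for ageing in iKO mice and 0 to 4 for genotype by age by limma, where 391 genes had an unadjusted p under 0.05 with all arrays. It gave 5 to 15 for colon iKO, 3 to 11 for genotype by tissue and 4901 to 6531 for colon against ileum.

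The correlation of the young iKO difference with ageing turned to -0.015 with normexp and -0.049 with the stricter filter, and that of the young with the aged iKO difference fell to 0.192 with no filter. With the mean over probes, Sdhc turned to -0.05 in genotype by age and Sirt1 to 0.02 in colon against ileum. With slide as a fixed factor in genotype by tissue, Fabp4 turned to -0.12, Lmod1 to -0.25 and the smooth muscle markers to a median of -0.05. Without 1 array, Pou2af1 ran from -0.01 (without young iKO 4) to 1.01 and the B and plasma cell markers from -0.01 (the same array) to 1.43 in young iKO. Sirt1 ran from -0.23 to 0.02 (without aged flox 1) in flox ageing and from -0.15 to 0.10 (without ileum aged flox 3) in colon against ileum.

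Among named genes, Mt1 alone of 7 called in young iKO passed in every setting, as did Mt1, Slc44a2 and Wfdc15b of 20 in the aged ileum, Prom2 of 15 in the colon, 16 of 24 in flox ageing and 19 of 24 in iKO ageing. In genotype by tissue 0 of 4 passed in every setting, and in colon against ileum 24 of 24 did. In the setting of each probe alone a named gene was still read from its brightest probe, so only the mean over probes drew on its other probes. Signal over background limited the dim genes: Prom2 was well above background on 0 ileum or aged colon flox arrays, and Lpar3 on 2 of 4 aged ileum iKO arrays.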

Other observations

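The tests of stretches of DNA that differ between the cohorts and of a sequence variant under the probe were chosen only after the result was seen.

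Some members of the lists passed limma with age in both genotypes and were not described above; they were not refitted without each array. Apob, the apolipoprotein of chylomicrons, differed by -2.40 ± 0.23 in flox mice and -2.43 ± 0.22 in iKO mice by its brightest probe (adjusted p = 3.99e-05 and 1.78e-05). Slc10a2, the ileal bile acid transporter, fell by 0.82 ± 0.19 and 0.80 ± 0.18 (adjusted p = 0.0237 and 0.0157), and Cdkn1a, a cell cycle inhibitor, by 0.96 ± 0.13 and 0.74 ± 0.12 (adjusted p = 0.000944 and 0.00297). Pdk4, a kinase that limits glucose oxidation, rose by 1.46 ± 0.30 and 1.09 ± 0.27 (adjusted p = 0.0125 and 0.0257). Ghrl, the hormone ghrelin, fell by 1.84 ± 0.34 and 1.06 ± 0.32 (adjusted p = 0.00797 and 0.0476).

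Large falls with age were sharp in both genotypes: 28 genes fell by at least 2 log2 units in each, among them Rps4l, Kifc5b and Tmem242, and 3 rose as far. Of these 28 genes 3 had another within 2 Mb, the receptor genes Klra7, Klra16 and Klra23, where random sets had a median of 2 and as many in a share of 0.29, so stretches of DNA that differ between the cohorts cannot be told apart from chance by this count. Of 12 other probes of 8 of these genes, 6 fell less than 50% as much (95% limits 21.1% to 78.9%, taking probes as independent). These were 3 probes of Apob at -0.29 to -0.47 and the other probes of Ipo7 (0.14 and -0.98) and St3gal3 (-0.7). The others fell by more than 50% as much. They were 1 more Apob probe (-2.41) and second probes of Kifc5b (-4.49), Tmem242 (-3.32), Snrpd3 (-2.71), Aph1a (-1.99) and Dnaaf5. Several probes shared a gene, so the limits may be too narrow and decide nothing. By gene the probes went both ways, and those of Apob were mixed. Over these genes as a set a sequence variant under the probe therefore cannot be told apart from a fall of the gene. Ageing stays open, as does position on the slide, which coincided with age.

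Other splits of the same arrays into groups of the same sizes were counted. For the 7 genes of young iKO the highest other split gave 138, with 2 of 35 splits as large, so this count did not exclude chance. All 7 passed with the same sign in the aged ileum arrays with position as a term, adjusted over these genes alone. That is no independent repeat, since the main fit that called them took its spread from all 15 ileum arrays. With only the young groups in the fit 3 genes passed. The highest other split parted slides 1 and 2 from slides 3 and 4, and equally replicate numbers 1 and 2 from 3 and 4, which points to a structure of the arrays without singling out slide (consensus slide correlation 0.012). With slide as a fixed factor 5 genes passed. The real split gave the most genes for aged ileum iKO (26, highest other 1), flox ageing (1323, highest other 98), iKO ageing (1664, highest other 26) and colon iKO (22, highest other 0 by limma). In the colon the real split had 1413 at an unadjusted p under 0.05. In each of these 1 of 35 splits was as large, the smallest share possible here and under the share of 0.05 set beforehand. These splits took no account of slide or replicate number. With slide as a fixed factor 9 genes passed in the aged ileum, 8 of them among the 26, and 1 in the colon. With replicate number as a block 16 passed in the aged ileum, 14 of them among the 26, and 1 in the colon. For genotype by age the splits could not test chance, since the real count was 0 by limma (391 at an unadjusted p under 0.05; highest other 49) and any split gives as many. For the 7 genes of genotype by tissue 2 of 100 splits were as large, the real one included, under the share of 0.05 set beforehand. This did not exclude chance, since the highest other gave 52, several times the real count, which points to a structure of the arrays. Slide as a fixed factor gave 3 genes, none of them among these 7. Replicate number as a block gave 0 by limma, with 1159 at an unadjusted p under 0.05. For colon against ileum the 10 splits were too few: the real count was 6460 and the highest other 0 by limma, with 8521 at an unadjusted p under 0.05 in the real split.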
